A study of Danio rerio with 16 samples.

How the data were processed

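Messenger RNA was measured by sequencing of polyA RNA from pools of 40 whole zebrafish embryos per library. Per the labels, embryos were WT, Gata5 morphants, Gata6 morphants or Gata5/6 morphants (called double morphants here), collected at bud or at 6-somites. A morphant is an embryo injected with a morpholino, an antisense oligomer that blocks translation or splicing of its target, so the target's mRNA need not be lower. The 16 libraries formed 8 groups of 2. Morpholino doses, clutches and injection days are not given in the labels.

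The deposited values are RPKM, reads per kilobase of gene model scaled to library size, computed by the authors from single 36-base reads on the Illumina Genome Analyzer IIx with genome build Zv9. The aligner, the annotation release and the counting tool are not given in the sources used here, and no gene coordinates on Zv9 were available, so positions are not reported here. The order of genes along chromosomes came from a RefSeq table of another build, GRCz12tu, matched by symbol and used in 1 test of neighbouring genes alone. The bud libraries list 26291 genes and the 6-somites libraries 26496, of which 25530 are in both, 761 in bud alone and 966 in 6-somites alone. No gene is listed at 0, and the smallest number of reads recovered was 1, so genes with a library at 0 reads appear to have been left out before deposition. A gene lost entirely in any library of a stage is therefore not analysed here. Names were assigned by gene identifier for 19258 of the 27257 identifiers, 7999 had no symbol and 2804 shared a symbol with another identifier. Some duplicated zebrafish genes carry the same symbol, so the copy is not always told apart. No identifier matched gata4 or gata6, and neither is reported here.

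Whole read numbers were recovered from the spacing of the RPKM values for 27251 identifiers (99.98%), with a tolerance of 0.01 reads. On simulated values for 500 genes the recovery was exact for 99.4%. Library depth recovered in this way was 19.7 to 30.8 M reads with a median of 28.5 M. A gene with 100 reads has a relative counting error of 10%, and this error does not include differences between pools of embryos. Recovered reads were used for depth and for limma-voom as an alternative, and all other values rest on the deposited RPKM.

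The design foresaw a model for read counts, and named limma on log2 values as the method if normalized values were deposited, as they were. Genes with at least 1 RPKM in at least 2 of the 16 libraries were tested, which left 14754 genes at bud, 14755 at 6-somites and 14751 in comparisons across stages. Values were transformed as log2(RPKM + 1), so a log2 change understates the ratio of RPKM for weakly expressed genes. limma 3.58.1 in R 4.3.3 with the trend option was fitted to all 16 libraries with a mean per group and 8 residual degrees of freedom. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. Errors of log2 changes are limma standard errors (SE), and errors of RPKM are SD over 2 libraries. The fit gave each gene the same spread at both stages, although libraries of a group differed more at bud. These SE and the adjusted p therefore tend to be too small at bud and too large at 6-somites.

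The 14 comparisons were each morphant group against WT at each stage, double against each kind of single morphant, the departure of the double morphants from the sum of both single morphant changes on the log2 scale, WT at 6-somites against WT at bud, and the change of the double morphant effect between stages. For double morphants against WT, the genes named were the 8 highest and 8 lowest log2 changes among called genes with at least 5 CPM (reads scaled to library size) and with both morphant libraries on one side of both WT libraries. The rule took 5 and 5 for each kind of single morphant and 4 and 4 for the other comparisons. It added gata5, tmem88a, tmem88b and up to 4 called members of each gene list in the double morphants. Where none passed, the 3 genes with the smallest p were taken. The rule passed over 26 genes without a symbol and gave 97 genes, of which 1 called for additivity at bud is not reported here. Genes named outside it are marked as chosen after their values were seen.

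Before the data were examined, 22 gene lists were fixed for the whole embryo. They covered cardiac progenitors, cardiac contractile genes, canonical Wnt targets, endoderm, blood and vascular progenitors, kidney, somites, neural plate, neural crest, the enveloping layer, the yolk syncytial layer, the hatching gland, germ cells, the p53 response, the interferon response, BMP, Nodal and FGF signalling, retinoic acid, pharyngeal mesoderm, notochord and the cell cycle. Each list was tested with limma's camera at a preset correlation of 0.01 in the 6 comparisons with WT, and the 132 results were adjusted together. camera compares a list with all other genes. camera with an estimated correlation and fry were run beside it. The comparisons, the rule for named genes and all alternatives but the omission of a pair of doubted libraries were also fixed before the data were examined.

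Alternatives were a filter at 5 RPKM, no filter, pseudocounts of 0.1 and 5, median-of-ratios scaling, limma-voom, a fit of the stage compared alone, the replicate number within each stage as a block, and the omission of a library in turn. For genes, only libraries of the groups compared were left out, and for gene lists each of the 16. Added after the data were seen was the omission of a pair of bud libraries. Gata5 bud 1 had the smallest share of its reads in listed genes (20.19 of 27.92 M), and double morphant bud 1 was the shallowest library (19.67 M). DESeq2 was not run, because the deposited values are not counts. Replicate deviations were compared between groups of the same stage across genes, which are not independent replicates. The correlations of 6 pairs of groups per stage were 0.19 to 0.56 at bud and 0.23 to 0.53 at 6-somites, and -0.18 to 0.1 across stages. The replicate numbers thus pair the libraries within a stage, and blocked values are printed beside each result that they move by over 1.5 times.

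The method was tested on simulated data with 200 changed genes, 50 at each of 4 fold changes. All genes of a stage had the same dispersion, the variance beyond counting over the squared mean. It was set to the median of well-covered genes, 0.02 at bud and 0.003 at 6-somites, without pairing of replicates. The shares below therefore need not hold for genes that vary more. At the bud dispersion, 34% of genes changed 1.5-fold were recovered, 92% at 2-fold and 100% at 4-fold and 8-fold. Of 206 simulated bud calls 43 were false (20.9%), which is above the nominal share. At the 6-somites dispersion, recovery was 18%, 92%, 100% and 100%, and 3 of 158 calls were false (1.9%). A count at bud can thus hold more false calls than its threshold states. Data were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.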

Results

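Whole zebrafish embryos labelled as Gata5, Gata6 or Gata5/6 morphants were compared with WT embryos at bud and at 6-somites, and the study title places them in a question on Tmem88a, cardiomyocyte progenitors and canonical WNT signalling. Each of the 8 groups held 2 libraries of 40 pooled embryos. Protein was not measured, so the extent of knockdown is unknown. Depth ranged from 19.7 to 30.8 M reads, and the 10 most abundant genes took 2.6% to 3.3% of the reads of a library. The first principal component held 50.5% of the variance over 14751 genes and separated the stages, with scores of -39.6 to -14.6 for bud libraries and 14.6 to 38.4 for 6-somites libraries. Libraries of a group differed more at bud, where the SD of their log2 difference was 0.341 to 0.475, than at 6-somites, where it was 0.183 to 0.228. Values below are RPKM (SD, n = 2) and log2 changes of RPKM + 1 with their SE. All named genes called in a comparison of a pair of groups had both libraries of one group on one side of both libraries of the other. The naming rule required this of the genes it picked, so it is no separate evidence.

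gata5 (ENSDARG00000017821), which encodes a zinc-finger factor of heart and endoderm development, had more mRNA in all 8 libraries with a Gata5 morpholino than in any WT library of the same stage. At bud it stood at 110.0 ± 6.0 RPKM in Gata5 morphants and 159 ± 1.5 RPKM in double morphants against 49.6 ± 4.7 RPKM in WT. At 6-somites it stood at 94.0 ± 4.2 RPKM in Gata5 morphants and 123 ± 9.5 RPKM in double morphants against 29.6 ± 3.8 RPKM in WT. All 4 differences from WT passed the test, with log2 changes of 1.13, 1.67, 1.64 and 2.02 ± 0.11. In Gata6 morphants gata5 was at 58.8 ± 0.31 RPKM at bud and 45.1 ± 1.3 RPKM at 6-somites, with adjusted p of 0.25 and 0.052. The double morphants did not pass the test against Gata5 morphants for gata5 at bud (0.54 ± 0.11, adjusted p = 0.055) or at 6-somites (0.39 ± 0.11, adjusted p = 0.086).

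tmem88a (ENSDARG00000056920), the gene of the study title, was at 1.05 ± 0.43 RPKM in double morphants and 3.66 ± 0.91 RPKM in WT at bud, a log2 change of -1.19 ± 0.3 with adjusted p = 0.078. The 8 alternatives other than leaving out a single library gave adjusted p from 0.05 to 0.51 for that value. Gata5 morphants at bud had 1.61 ± 0.052 RPKM of tmem88a (adjusted p = 0.33) and Gata6 morphants 4.15 ± 2.9 RPKM (adjusted p = 0.96). At 6-somites the double morphants had 2.31 ± 0.22 RPKM against 3.43 ± 0.24 RPKM in WT, with adjusted p = 0.53 in the fit of all libraries and 0.02 in a fit of the 6-somites libraries alone. tmem88b (ENSDARG00000069388), its paralog, fell in the double morphants at 6-somites from 4.74 ± 0.48 to 2.84 ± 0.052 RPKM, a log2 change of -0.58 ± 0.14 with adjusted p = 0.047, and was not past the threshold in any other comparison with WT. That call was lost without any 1 of the 4 libraries compared, with adjusted p up to 0.33.

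**Figure D1:**
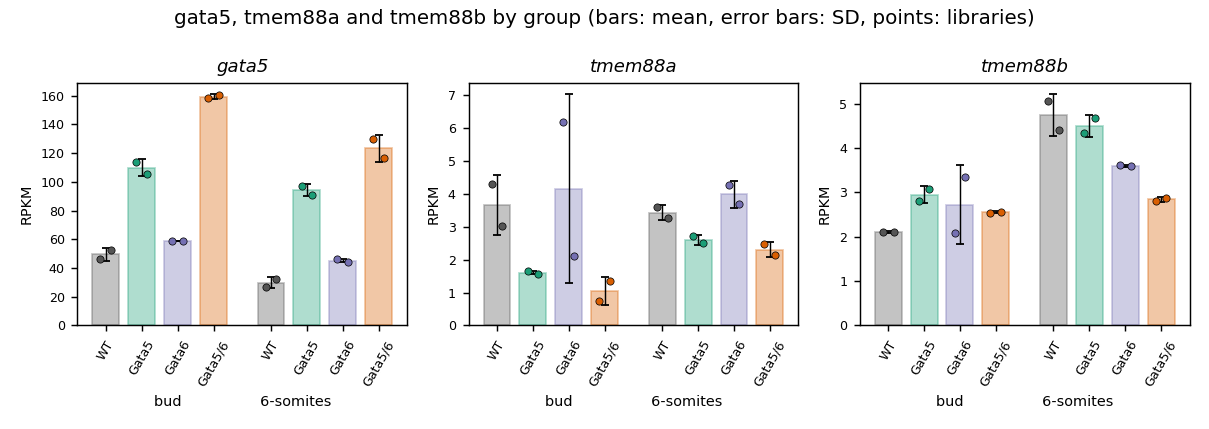
RPKM of gata5, tmem88a and tmem88b (vertical axes, RPKM) in WT, Gata5, Gata6 and Gata5/6 morphants at bud and 6-somites, with bars for means, error bars for SD and points for the 2 libraries. gata5 was highest in the double morphants, at 159 RPKM at bud and 123 RPKM at 6-somites, and tmem88a was lowest in the double morphants at bud, at 1.05 RPKM.

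The comparison of Gata5 morphants with WT at bud asked what the Gata5 morpholino alone changed at the end of gastrulation. The largest rise was in the uncharacterised gene zgc:56231, from 0.518 ± 0.18 to 11.5 ± 1.7 RPKM (log2 change 3.04 ± 0.15, adjusted p = 4.8e-06). creb3l3l, related to membrane-bound transcription factors of liver and gut metabolism, rose from 5.99 ± 0.89 to 13.4 ± 1.6 RPKM, and sub1, a transcriptional coactivator, rose from 24.0 ± 1.4 to 55.2 ± 2.8 RPKM. The RNA helicase gene ddx3xa also rose (0.95 ± 0.13). prdx6, a peroxidase gene, fell from 10.5 ± 3.3 to 2.8 ± 0.79 RPKM and the tetraspanin gene tspan15 from 4.61 ± 0.12 to 1.28 ± 0.61 RPKM. The acetylcholine receptor gene chrna2 (-1.76 ± 0.32), the purine nucleoside phosphorylase gene pnp4a (-1.27 ± 0.23) and pigl (-1.04 ± 0.16) fell too.

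Among the gene lists, BMP signalling was lower in Gata5 morphants at bud than other genes (camera adjusted p = 0.00656), with 0 of 21 members called, 6 lower and 0 higher at an unadjusted limma p under 0.05, 1 lower with voom and 2 lower adjusted over the list alone. Notochord genes were higher as a list (adjusted p = 0.00198), with 0 of 17 called, 6 higher at an unadjusted limma p under 0.05, 0 with voom and 5 adjusted over the list alone. Germ cell genes were higher as a list (adjusted p = 0.0225), with 0 of 7 called, 2 higher at an unadjusted limma p under 0.05, 1 with voom and 2 adjusted over the list alone. With an estimated correlation the adjusted p were 0.563 for BMP signalling, 0.386 for the notochord and 0.596 for germ cells. The BMP call was lost without WT bud 2 (adjusted p = 0.221), the notochord call without Gata5 bud 1 (0.107) and the germ cell call without Gata5 bud 2 (0.188) or WT bud 2 (0.111). The cell cycle gene ccnb2, named after its values were seen, rose by 0.51 ± 0.09 (adjusted p = 0.032) and was the only list member called.

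limma called 53 of 14754 genes in Gata5 morphants at bud, 20 higher and 33 lower, and 1578 genes had an unadjusted p under 0.05. With median-of-ratios scaling the higher share moved from 37.7% to 53.6%, and with a filter at 5 RPKM to 27.1%. The count was 88 with the replicate number as a block, 1 in a fit of the bud libraries alone and 27 without both doubted libraries. Those 27 turned the balance, with 21 higher and 6 lower, and shared 13 with the 53. The count was 8 without WT bud 2 to 29 without Gata5 bud 2 when any 1 of the 4 libraries was left out. Of the 10 genes named here, zgc:56231, gata5, creb3l3l and tspan15 kept their call whichever library was left out, and the others reached adjusted p of 0.074 to 0.22. In the fit of the bud libraries alone zgc:56231 was the 1 of the 10 called.

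The Gata6 morphants at bud were examined in the same way. cdh17, a cadherin of kidney and gut epithelium, rose from 0.708 ± 0.16 to 5.82 ± 1.2 RPKM (log2 change 1.99 ± 0.21, adjusted p = 0.0015). etsrp, a master regulator of blood vessel and blood precursors, rose from 2.0 ± 1.4 to 7.96 ± 3.9 RPKM, and gadd45a, a growth arrest and DNA damage gene, rose from 1.49 ± 0.47 to 7.57 ± 3.8 RPKM. metrnlb (2.04 ± 0.36) and the transcription factor gene nfybb (1.65 ± 0.3) rose as well. rexo2, an oligoribonuclease gene, fell from 24.4 ± 1.0 to 2.5 ± 1.4 RPKM (-2.92 ± 0.34), and scpep1, a serine carboxypeptidase gene, fell from 75.6 ± 5.7 to 16.3 ± 4.1 RPKM (-2.17 ± 0.16). The fatty acid receptor gene cd36 fell from 5.32 ± 2.0 to 0.607 ± 0.023 RPKM, and lrrc15 (-2.07 ± 0.45) and tcf20 (-1.9 ± 0.33) fell.

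Of 22 blood and vascular genes 3 rose in Gata6 morphants at bud, namely etsrp, tal1 and lmo2, and the list as a whole was not called (camera adjusted p = 0.713), with 4 higher and 3 lower adjusted over the list alone. tal1, which specifies blood, was at 2.5 ± 0.23 RPKM against 0.328 ± 0.19 RPKM in WT, and its partner lmo2 was at 5.13 ± 1.2 against 2.06 ± 0.24 RPKM. Of the 8 kidney genes cdh17 and mecom rose, of the 15 neural crest genes sox10 rose from 0.92 ± 0.5 to 3.94 ± 0.97 RPKM, and of the 34 neural plate genes en2 and mab21l2 rose and her4.1 and gbx1 fell. The Nodal list had 2 of 12 members lower, lft2 and noto, and the somite list had myog and actc1 higher and her1 and hes6 lower among 25. Further single members that rose were ca2 of the enveloping layer, isg15 of the interferon response and nr2f2 of the retinoic acid list. nkx2.3 of the endoderm and pharyngeal lists rose from 0.0951 ± 0.026 to 0.942 ± 0.33 RPKM, and in the notochord list col8a1a rose and noto fell. Apart from cdh17 and etsrp, the list members of this comparison were named after their values were seen. The Gata6 libraries at bud had first-component scores of -14.6 and -26.9, against -24.6 and -39.6 for WT at bud.

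Cell cycle genes were lower as a list in Gata6 morphants at bud (camera adjusted p = 0.00656, and 0.596 with an estimated correlation), with 2 of 28 members lower, pcna and rrm1, and 1 higher, mcm6. Adjusted over the list alone, 6 were lower and 1 higher. pcna, the DNA polymerase clamp, was at 338 RPKM against 590.0 RPKM in WT, with a log2 change of -0.82 ± 0.15. The p53 response was higher as a list (adjusted p = 0.00656, and 0.712 with an estimated correlation), with tp53inp1 alone called among 20 and 10 higher and 1 lower adjusted over the list alone. Both list calls were lost without Gata6 bud 1, with adjusted p = 0.436 for the cell cycle and 0.395 for p53, and the p53 call also without WT bud 1 (0.059). In Gata6 bud 1 the p53 feedback gene mdm2 was at 16.1 RPKM, against 5.18 RPKM in Gata6 bud 2 and 3.32 and 2.41 RPKM in WT. Double morphant bud 1 had 8.31 RPKM of mdm2 against 3.23 RPKM in double morphant bud 2.

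limma called 241 of 14754 genes in Gata6 morphants at bud, 126 higher and 115 lower, and 2858 had an unadjusted p under 0.05. The count was 472 with the block, 414 with limma-voom, 0 in a fit of the bud libraries alone and 409 without both doubted libraries. It was 17 without WT bud 2 to 2224 without Gata6 bud 1 when a library was left out. Of 10 named genes cdh17, rexo2, scpep1 and cd36 kept their call whichever of the 4 libraries compared was left out, and the others lost theirs in at least 1 omission.

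In double morphants at bud, fabp2, an intestinal fatty acid binding protein gene, fell most of the named genes against WT, from 98.3 ± 61.0 to 7.49 ± 4.8 RPKM (-3.52 ± 0.46, adjusted p = 0.0032), acsl5, an acyl-CoA synthetase gene, from 13.9 ± 6.3 to 1.6 ± 0.018 RPKM, and cd36 from 5.32 ± 2.0 to 0.361 ± 0.18 RPKM. soat1, which esterifies cholesterol, fell from 3.5 ± 0.21 to 0.248 ± 0.085 RPKM. Sulfate transporter gene slc26a1, a member of the yolk syncytial list, rose from 28.4 ± 1.4 to 88.4 ± 21 RPKM, and cdh17 rose from 0.708 ± 0.16 to 9.38 ± 3.9 RPKM (2.55 ± 0.21, adjusted p = 0.00022). kdr, a VEGF receptor gene of endothelial precursors, fell from 3.12 ± 0.37 to 0.334 ± 0.0082 RPKM (-1.62 ± 0.19, adjusted p = 0.0016).

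Further rises in double morphants at bud were in proz, a vitamin K-dependent plasma protein gene (2.19 ± 0.33), ENSDARG00000093214 (2.18 ± 0.29), zgc:56231 (2.15 ± 0.15), the metallothionein gene mt1x (1.88 ± 0.34) and lrrc17 (1.78 ± 0.21). Falls were in si:dkey-238o13.4 (-2.49 ± 0.32), the D-amino acid oxidase gene dao (-2.11 ± 0.44), rexo2 (-1.86 ± 0.34) and the circadian repressor gene bhlhe41 (-1.86 ± 0.19). Of 18 cardiac progenitor genes nkx2.7, an early heart field factor, fell from 12.3 ± 4.5 to 4.87 ± 1.3 RPKM (adjusted p = 0.034), and 0 were called higher by limma or voom. At an unadjusted p under 0.05, 2 were higher and 3 lower, and adjusted over the list alone 1 was higher and 2 lower. The mean of that list was -0.12 and its median 0.03, so they differ in sign. nkx2.5 was at 0.0973 ± 0.051 RPKM against 0.0418 ± 0.0037 RPKM in WT, near the detection limit at this stage.

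BMP signalling genes were lower as a list in double morphants at bud (camera adjusted p = 0.000778, and 0.548 with an estimated correlation). The BMP targets id3, from 107 ± 13.0 to 63.9 ± 6.0 RPKM, and id2, from 9.29 ± 1.3 to 5.96 ± 0.39 RPKM, were the 2 of 21 members called, and 5 were lower adjusted over the list alone. Blood and vascular genes were lower as a list (adjusted p = 0.0327, and 0.563 with an estimated correlation), with kdr the 1 of 22 called and 4 lower adjusted over the list alone. Kidney genes were higher as a list (adjusted p = 0.0156, and 0.563 with an estimated correlation), with cdh17 and mecom, a kidney and blood regulator, called among 8. mecom rose from 0.785 ± 0.05 to 3.52 ± 0.63 RPKM. Adjusted over the list alone, 2 kidney genes were higher and 1 lower. The blood and vascular call was lost without WT bud 2 (adjusted p = 0.169), double morphant bud 1 (0.0638) or double morphant bud 2 (0.0682). The kidney call was lost without WT bud 2 (0.0989) or double morphant bud 2 (0.0524). With the bud libraries fitted alone, 1 kidney gene was higher in double morphants and 0 members of any other list were called. That fit called 0 list members in either kind of single morphant.

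Other list members called in double morphants at bud were sox19b (0.38 ± 0.08) among 34 neural plate genes, zic5 (0.6 ± 0.12) higher and id3 lower among 15 neural crest genes. They were also ca2 (0.73 ± 0.13) among 22 enveloping layer genes, and slc26a1 and the apolipoprotein gene apoc2 (0.85 ± 0.18) among 23 yolk genes. At an unadjusted p under 0.05, 2 yolk genes were higher and 8 lower, or 2 and 3 adjusted over the list alone. The yolk list had a median of -0.15 and was not called (camera adjusted p = 0.427, and 0.898 with an estimated correlation). Canonical Wnt genes had 0 of 19 members called by limma or by voom, with 4 higher and 0 lower at an unadjusted p under 0.05. The adjusted p of the Wnt list was 0.0624, and 0.0501 with the block, with a median of 0.20. The p53 list, with a median of 0.29, also had an adjusted p of 0.0624 (0.754 with an estimated correlation), and with the block it was called (0.0489). limma and voom called 0 of its 20 members, with 2 higher at an unadjusted p under 0.05.

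limma called 235 of 14754 genes in double morphants at bud, 113 higher and 122 lower, and 2148 had an unadjusted p under 0.05. The count was 362 with the block, 6 in a fit of the bud libraries alone and 87 without both doubted libraries. It was 61 without WT bud 1 to 385 without double morphant bud 2 when a library was left out. Among the 25 named genes, fabp2, acsl5, cd36, cdh17, kdr and mecom were some of those that kept their call whichever of the 4 libraries compared was left out. Others, nkx2.7, id2 and id3 included, lost theirs in at least 1 omission. In the fit of the bud libraries alone 3 of the 25 were called, cdh17, zgc:56231 and gata5.

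**Figure D2:**
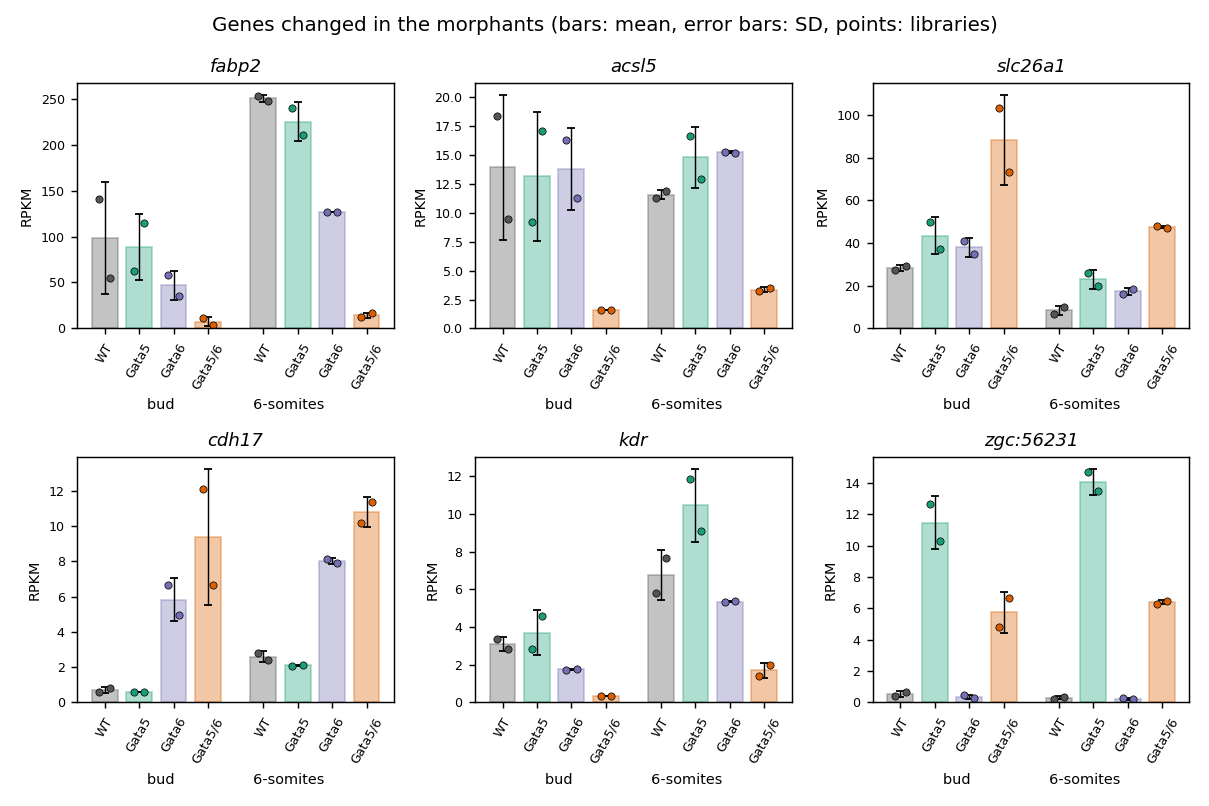
RPKM of fabp2, acsl5, slc26a1, cdh17, kdr and zgc:56231 (vertical axes, RPKM) in the 8 groups, with bars for means, error bars for SD and points for the 2 libraries. In double morphants fabp2 stood at 7.49 RPKM at bud and 14.1 RPKM at 6-somites, the lowest of the 4 groups at each stage, and slc26a1 at 88.4 and 47.5 RPKM, the highest.

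Double morphants were next compared with each kind of single morphant at bud, which asked what the other morpholino added. Against Gata5 morphants, fabp2 was lower (7.49 ± 4.8 against 88.7 ± 36.0 RPKM, log2 change -3.46 ± 0.46), as were acsl5 (-2.39 ± 0.29), cd36 (-2.27 ± 0.23) and ppp1r3ab, a glycogen-targeting phosphatase subunit (-2.22 ± 0.32). cdh17 was higher (9.38 ± 3.9 against 0.609 ± 0.0044 RPKM, 2.64 ± 0.21), as were proz, ENSDARG00000093214 and mt1x. Against Gata6 morphants, fabp2 (-2.58 ± 0.46), acsl5 (-2.48 ± 0.29), the parvalbumin gene pvalb9 (-2.49 ± 0.45) and etsrp (1.03 ± 0.13 against 7.96 ± 3.9 RPKM, -2.07 ± 0.29) were lower. zgc:56231 (2.31 ± 0.15), lrrc15 (2.17 ± 0.45), basp1 (1.56 ± 0.28), avd (1.46 ± 0.2) and gata5 (1.42 ± 0.11) were higher. tmem88a did not pass the test against Gata6 morphants (-1.22 ± 0.3, adjusted p = 0.055) or against Gata5 morphants (-0.36 ± 0.3, adjusted p = 0.69).

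Against Gata5 morphants at bud limma called 109 genes, 51 higher and 58 lower, and 1781 had an unadjusted p under 0.05. Against Gata6 morphants it called 385, 163 higher and 222 lower, and 2830 had an unadjusted p under 0.05. A fit of the bud libraries alone called 0 in each, and the fit without both doubted libraries called 35 and 241. The 35 were 5 higher and 30 lower, so the near balance against Gata5 morphants was not kept. A filter at 5 RPKM gave 69 against Gata5 morphants, and no filter gave 133 higher and 122 lower against Gata6 morphants. When a library was left out the counts were 16 without double morphant bud 1 to 235 without double morphant bud 2 against Gata5 morphants, and 146 without double morphant bud 1 to 2123 without Gata6 bud 1 against Gata6 morphants. cdh17 and cd36 against Gata5 morphants, and zgc:56231, avd, acsl5, etsrp and gata5 against Gata6 morphants, kept their calls whichever library of the groups compared was left out.

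The response of double morphants at bud departed from the sum of the single responses in 4 genes, all lower than the sum. The midbrain gene en2 (-1.74 ± 0.16, adjusted p = 0.0035) and tal1 (-1.86 ± 0.18, adjusted p = 0.0035) stood at 2.82 ± 0.1 and 2.5 ± 0.23 RPKM in Gata6 morphants and at 0.122 ± 0.055 and 0.0882 ± 0.066 RPKM in double morphants. The axon guidance gene ntn1 (-1.13 ± 0.16, adjusted p = 0.047), named after its values were seen, was at 0.336 ± 0.16 RPKM in double morphants. None of the 4 met all limits of the naming rule.

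limma had 1689 genes at an unadjusted p under 0.05 in that test. The count of 4 was 7 with the block, 38 with limma-voom, 17 with median-of-ratios scaling, 46 at a pseudocount of 0.1, and 0 at a pseudocount of 5 or in a fit of the bud libraries alone. It moved with the bud library left out, while en2 and tal1 kept their call whichever bud library was left out.

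At 6-somites, Gata5 morphants differed from WT in a few strongly raised genes. zgc:56231 rose from 0.285 ± 0.096 to 14.1 ± 0.83 RPKM (3.56 ± 0.15, adjusted p = 8.3e-07), pkp3a, a desmosomal plakophilin gene, from 11.2 ± 0.4 to 31.2 ± 2.5 RPKM, and slc26a1 from 8.43 ± 2.3 to 22.9 ± 4.3 RPKM. The telomerase-associated gene tep1 rose by 1.18 ± 0.18. tdp1, a DNA repair enzyme gene, fell from 18 ± 0.0058 to 6.7 ± 0.34 RPKM, and fgfrl1b, an FGF receptor-like gene, fell from 8.96 ± 0.4 to 3.55 ± 0.068 RPKM. mpdu1a (-1.06 ± 0.19), si:dkey-100n23.4 (-0.9 ± 0.16) and the actin regulator gene coro1c (-0.81 ± 0.12) also fell.

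The p53 response was higher as a list in Gata5 morphants at 6-somites (camera adjusted p = 0.000636, and 0.639 with an estimated correlation), with sesn2, a stress-induced sestrin gene, called among 20 and 4 higher adjusted over the list alone. Canonical targets chosen after their values were seen did not pass over all genes: cdkn1a was at 4.91 ± 0.021 RPKM against 1.29 ± 0.16 RPKM in WT (adjusted p = 0.29), and mdm2 at 8.2 ± 1.2 against 3.49 ± 0.18 RPKM (adjusted p = 0.37). The spread behind these adjusted p was pooled with bud. There the Gata6 libraries 1 and 2 had cdkn1a at 8.79 and 2.58 RPKM and mdm2 at 16.1 and 5.18 RPKM, which widened it. In a fit of the 6-somites libraries alone, 12 of the 20 were higher and 0 lower. BMP signalling (adjusted p = 0.00198, and 0.563 with an estimated correlation), FGF signalling (0.0146, and 0.563), neural crest (0.0128, and 0.548) and neural plate (0.00959, and 0.563) were lower as lists with no member called by limma. At an unadjusted p under 0.05 those 4 lists had 7, 2, 2 and 4 members lower and 2, 0, 0 and 0 higher, and voom called 1 member, in BMP signalling. Adjusted over the list alone, BMP signalling had 1 higher and 2 lower, FGF signalling 1 lower, and the others 0. In a fit of the 6-somites libraries alone, the 4 lists had 6, 2, 2 and 5 members lower and 1, 0, 0 and 1 higher. Kidney genes were lower as a list (adjusted p = 0.0202, and 0.563), with osr1 the 1 of 8 called, and yolk genes higher (0.0421, and 0.731), with slc26a1 the 1 of 23 called. Adjusted over the list alone, 1 kidney gene was higher and 2 lower, and 2 yolk genes were higher. The fit of the 6-somites libraries alone gave 1 higher and 4 lower kidney genes, and 6 and 2 yolk genes.

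Of these calls in Gata5 morphants at 6-somites, FGF signalling was lost without WT 6-somites 2 (adjusted p = 0.0689) or Gata5 6-somites 1 (0.0523). The neural crest was lost without WT 6-somites 1 (0.0566) or Gata5 6-somites 1 (0.0835), and the neural plate without WT 6-somites 1 (0.0844). The yolk call was lost without WT 6-somites 1 (0.165), Gata5 6-somites 1 (0.18), or any of 4 bud libraries, namely Gata5 bud 1 (0.0561), Gata6 bud 1 (0.0543), double morphant bud 1 (0.0513) and double morphant bud 2 (0.0524). spns2 of the cardiac progenitor list (0.61 ± 0.11) and ccnb2 of the cell cycle list (0.63 ± 0.09) rose, and they, sesn2 and osr1 were named after their values were seen. The cardiac progenitor list itself tended down without a call (median -0.15, camera adjusted p = 0.0643, and 0.596 with an estimated correlation). Of its members 1 was higher and 2 lower adjusted over the list alone, and 1 and 4 in a fit of the 6-somites libraries alone.

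limma called 70 of 14755 genes in Gata5 morphants at 6-somites, 53 higher and 17 lower, and 1640 had an unadjusted p under 0.05. The count was 115 with the block, 1271 in a fit of the 6-somites libraries alone, 37 with a filter at 5 RPKM, 121 with no filter, and 127 at a pseudocount of 5. It was 3 without WT 6-somites 2 to 9 without WT 6-somites 1 when any 1 of the 4 libraries was left out. All 10 named genes were called in the fit of the 6-somites libraries alone, while zgc:56231, gata5 and pkp3a kept their call whichever library was left out and the others reached 0.052 to 0.43.

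Gata6 morphants at 6-somites again had more cdh17 than WT, at 8.03 ± 0.18 against 2.59 ± 0.31 RPKM (1.33 ± 0.21, adjusted p = 0.027). ifi30a, a lysosomal thiol reductase gene, rose from 52.6 ± 3.1 to 126 ± 13.0 RPKM, mfsd2al1, a lipid transporter gene, from 0.808 ± 0.26 to 3.5 ± 0.1 RPKM, and slc47a1, a cation transporter gene, from 7.93 ± 1.6 to 17.6 ± 0.66 RPKM. zgc:174904 rose by 1.09 ± 0.19. rexo2 fell from 22.1 ± 1.8 to 4.79 ± 1.1 RPKM, the actin-bundling gene pls3 from 38.8 ± 1.2 to 14.8 ± 0.063 RPKM, and the valyl-tRNA synthetase gene vars1 from 21.8 ± 0.33 to 7.8 ± 0.8 RPKM. focad (-1.64 ± 0.26) and ginm1 (-1.56 ± 0.23) also fell.

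Yolk syncytial genes were higher as a list in Gata6 morphants at 6-somites (camera adjusted p = 0.000119, and 0.563 with an estimated correlation). Of its 23 members limma and voom called 0, with 8 higher and 1 lower at an unadjusted p under 0.05, and 6 higher and 1 lower adjusted over the list alone. The p53 response was higher (adjusted p = 0.00331, and 0.684), with 0 of 20 called by limma or voom, 6 higher and 1 lower at an unadjusted p under 0.05, 2 higher adjusted over the list alone, and 11 higher and 1 lower in a fit of the 6-somites libraries alone. Lower as lists were BMP signalling (0.00805, and 0.563 with an estimated correlation), the cell cycle (0.0156, and 0.641), the neural plate (0.0443, and 0.659), the notochord (0.0225, and 0.548) and somites (0.0146, and 0.563). limma and voom called 0 members of these 5 lists, and 6, 5, 3, 8 and 5 members were lower and 0 higher at an unadjusted p under 0.05. In a fit of the 6-somites libraries alone, 6, 3, 1, 5 and 5 were lower, 1 neural plate gene was higher, and 9 yolk genes were higher and 1 lower. Adjusted over the list alone, 1 cell cycle, 4 notochord and 1 somite gene were lower. The neural plate call was lost without 8 of the 16 libraries, at 0.165 without WT 6-somites 1, 0.077 and 0.0621 without Gata6 6-somites 2 and 1, and 0.0519 to 0.0589 without both Gata5 bud, both double morphant bud or the Gata5 6-somites 1 libraries, each left out alone. The BMP call was lost without WT 6-somites 2 (0.0538) and the somite call without WT 6-somites 1 (0.0513).

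limma called 50 of 14755 genes in Gata6 morphants at 6-somites, 23 higher and 27 lower, and 1340 had an unadjusted p under 0.05. The count was 964 in a fit of the 6-somites libraries alone, 28 with a filter at 5 RPKM, and 32 and 98 at pseudocounts of 0.1 and 5. The near balance was not kept with no filter (17 higher and 44 lower) or at a pseudocount of 5 (33 and 65). The count was 1 without WT 6-somites 1 to 2 without WT 6-somites 2 when any 1 of the 4 libraries was left out. All 10 named genes were called in the fit of the 6-somites libraries alone, and each lost its call in all 4 omissions, with adjusted p of up to 0.14 to 0.56.

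**Figure D3:**
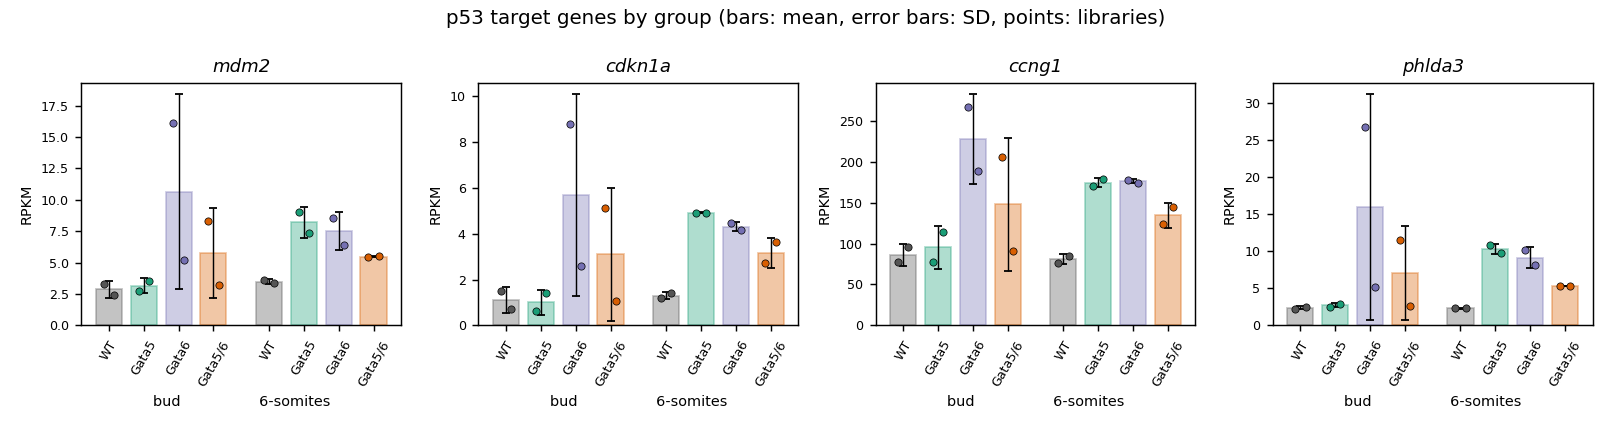
RPKM of the p53 targets mdm2, cdkn1a, ccng1 and phlda3 (vertical axes, RPKM) in the 8 groups, with bars for means, error bars for SD and points for the 2 libraries. At bud Gata6 library 1 stood apart with mdm2 at 16.1 RPKM, and at 6-somites mdm2 was at 5.43 and 5.54 RPKM in the double morphants, below the 6.44 to 9.05 RPKM of the single morphants and above the 3.37 and 3.62 RPKM of WT.

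Double morphants at 6-somites had lower values of several early heart field genes than WT. Their libraries scored 14.6 and 21.8 on the first component, nearer to bud than the 38.4 and 34.7 of WT at 6-somites. nkx2.5 was near the detection limit at bud, so a delay of these embryos would lower it too and was not separated from a heart effect. nkx2.5, a core cardiac transcription factor gene, fell from 1.18 ± 0.12 to 0.162 ± 0.082 RPKM (-0.91 ± 0.13, adjusted p = 0.0038), and tbx20, a T-box gene of the heart, from 2.23 ± 0.28 to 0.578 ± 0.073 RPKM (-1.03 ± 0.18, adjusted p = 0.0089). mespaa, a gene of early cardiac mesoderm and somites, fell from 4.58 ± 1.1 to 1.79 ± 0.26 RPKM (-0.99 ± 0.24, adjusted p = 0.048), and tmem88b fell as given above. These were 4 of 18 cardiac progenitor genes measured, 4 adjusted over the list alone. voom called 2 lower, and 8 were lower and 0 higher at an unadjusted p under 0.05. The list was lower as a whole (camera adjusted p = 0.0376, and 0.563 with an estimated correlation). Of 3 contractile genes the calcium pump gene atp2a2a fell from 3.03 ± 0.26 to 1.73 ± 0.084 RPKM, and that list was also lower (adjusted p = 0.0421, and 0.563).

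Not past the threshold over all genes were the heart factor hand2, at 13.9 ± 0.62 against 21.3 ± 0.4 RPKM (adjusted p = 0.27), and nkx2.7, at 18.3 ± 2.2 against 21.4 ± 2.2 RPKM (adjusted p = 0.71). The same held for tbx1, at 4.33 ± 0.26 against 4.28 ± 0.57 RPKM (adjusted p = 0.98). These 3 genes were chosen after their values were seen. In a fit of the 6-somites libraries alone, 9 of 18 cardiac progenitor genes were lower and 1 higher, and all 3 contractile genes were lower. The cardiac progenitor call was lost without double morphant 6-somites 2 (0.055), WT 6-somites 1 (0.0512), Gata5 bud 1 (0.053), or double morphant bud 1 (0.0519) or 2 (0.0524). The contractile call was lost without double morphant 6-somites 2 (0.0892), WT 6-somites 1 (0.0873), Gata5 6-somites 1 (0.0523), Gata5 bud 1 (0.0561), or double morphant bud 1 (0.0519) or 2 (0.0524). nkx2.5 lost its call without double morphant 6-somites 1 (adjusted p = 0.056), tbx20 without 3 libraries (up to 0.1), mespaa without 4 (up to 0.36) and atp2a2a without 3 (up to 0.13).

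**Figure D4:**
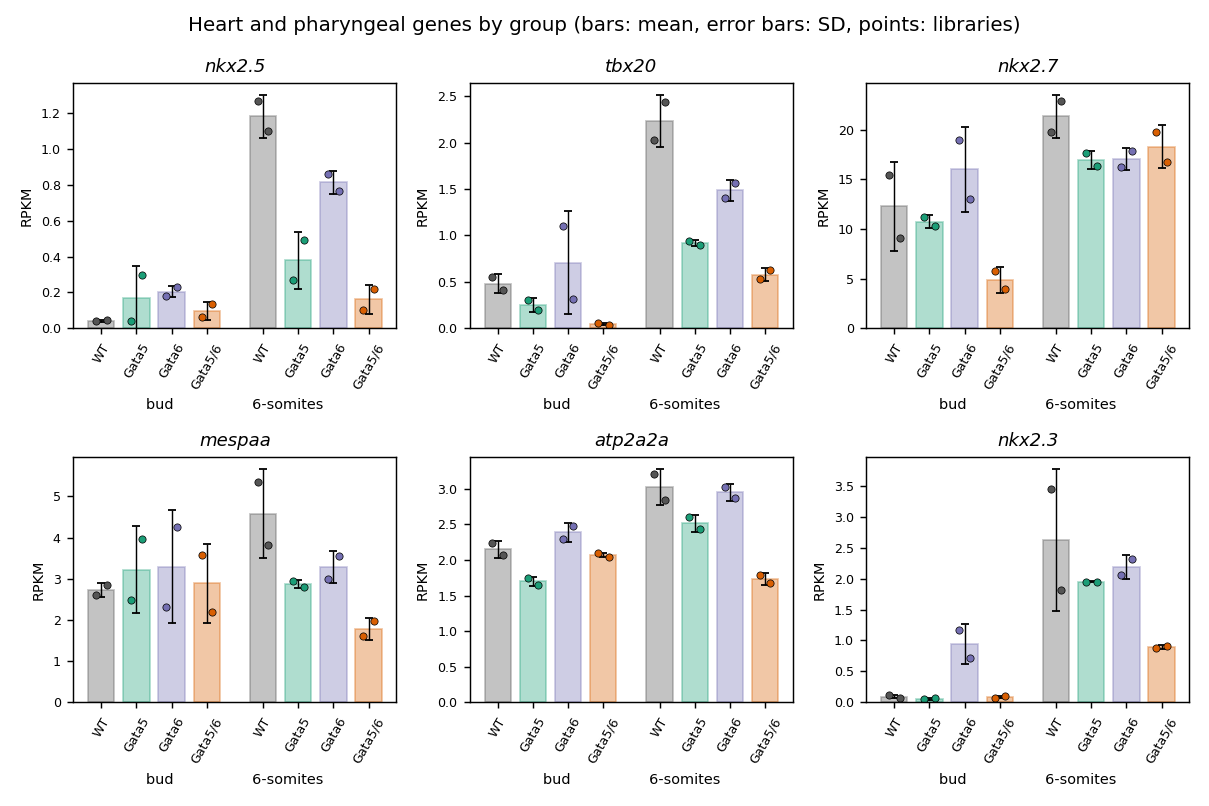
RPKM of nkx2.5, tbx20, nkx2.7, mespaa, atp2a2a and nkx2.3 (vertical axes, RPKM) in the 8 groups, with bars for means, error bars for SD and points for the 2 libraries. At 6-somites nkx2.5 stood at 0.162 RPKM in double morphants against 1.18 RPKM in WT and tbx20 at 0.578 against 2.23 RPKM, while nkx2.7 was at 18.3 against 21.4 RPKM.

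Of 22 vascular and blood genes 2 fell in double morphants at 6-somites, and the list was not called (camera adjusted p = 0.118). kdr fell from 6.75 ± 1.3 to 1.7 ± 0.4 RPKM (-1.52 ± 0.19) and gata1a, the erythroid regulator, from 1.35 ± 0.27 to 0.458 ± 0.087 RPKM. tal1, chosen after its values were seen, differed by 0.01 ± 0.13 (adjusted p = 0.98). In the pharyngeal list nkx2.3, also an endoderm list member, fell from 2.63 ± 1.2 to 0.894 ± 0.031 RPKM and tcf21, a head muscle and epicardial factor gene, from 1.0 ± 0.21 to 0.234 ± 0.039 RPKM, 2 of 13. The BMP genes smad6 (-0.5 ± 0.11) and id2 (-0.47 ± 0.11) fell among 21, the retinal gene rx1 (-0.64 ± 0.14) among 34 neural plate genes, and pdgfra (-0.73 ± 0.18) among 15 neural crest genes. Rises were in cdh17 among 8 kidney genes, from 2.59 ± 0.31 to 10.8 ± 0.85 RPKM, and ca2 (0.73 ± 0.13) among 22 enveloping layer genes. Rises were also in the Wnt antagonist gene frzb (1.04 ± 0.15) among 10 hatching gland genes, shh (0.57 ± 0.12) among 17 notochord genes and sesn3 (0.95 ± 0.17) among 20 p53 genes. In a fit of the 6-somites libraries alone, 9 p53 genes were higher and 1 lower, 6 and 2 in the neural plate, 1 and 6 in the neural crest, 1 and 4 in BMP signalling, and 2 and 4 of 18 in the blood and vascular list. The same fit had 2 kidney genes higher and 2 lower, 2 and 4 in the enveloping layer, 2 and 1 in the hatching gland, and 1 and 3 in the notochord. These lists were not called as a whole. Adjusted over the list alone, 3 blood and vascular genes were lower, and in the pharyngeal list 3 were higher and 2 lower. ccnb2 rose from 11 ± 0.19 to 18 ± 0.43 RPKM among 28 cell cycle genes, and that list was higher (camera adjusted p = 0.00198, and 0.563 with an estimated correlation) with 3 higher adjusted over the list alone.

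Yolk syncytial genes moved both ways in double morphants at 6-somites. slc26a1 rose from 8.43 ± 2.3 to 47.5 ± 0.52 RPKM (2.38 ± 0.21, adjusted p = 0.00035) and apoc2 from 40.6 ± 1.8 to 91.4 ± 0.17 RPKM. The yolk syncytial transcription factor gene mxtx1 rose from 1.96 ± 0.44 to 4.32 ± 0.03 RPKM, and mttp, which loads lipid onto apolipoprotein B and was named after its values were seen, from 21 ± 5.2 to 43.0 ± 2.8 RPKM. The apolipoprotein genes apoa4b.2, from 10.6 ± 1.0 to 1.94 ± 0.042 RPKM, and apoa4b.1, from 32.8 ± 0.89 to 9.36 ± 1.8 RPKM, fell. These were 4 of 23 members higher and 2 lower, or 5 and 5 adjusted over the list alone, with an adjusted p of 0.193 for the list, and 10 and 5 in a fit of the 6-somites libraries alone. Outside the list, fabp2 fell from 250.0 ± 4.1 to 14.1 ± 3.0 RPKM (-4.07 ± 0.46, adjusted p = 0.00095), and dao fell from 31.3 ± 1.5 to 5.17 ± 1.4 RPKM.

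Outside the lists, the plasma protein genes proz (2.83 ± 0.33) and ahsg1 (2.71 ± 0.68), zgc:56231 (2.53 ± 0.15), basp1 (2.24 ± 0.28), ifi30a (1.99 ± 0.2) and the potassium channel partner gene kcnip3b (1.97 ± 0.35) rose in double morphants at 6-somites. zgc:113293 (-3.21 ± 0.76), ppp1r3ab (-2.15 ± 0.32), the hindbrain and blood factor gene mafbb (-1.85 ± 0.38) and s100a1 (-1.71 ± 0.41), a calcium-binding protein gene of muscle, fell. Canonical Wnt genes had 0 of 19 called by limma or voom, with 0 higher and 2 lower at an unadjusted p under 0.05, and 3 higher and 2 lower in a fit of the 6-somites libraries alone. FGF (15 genes), interferon (9), Nodal (12), germ cell (7), retinoic acid (23) and somite (25) lists had 0 members called by limma, and none of these lists was called. At an unadjusted p under 0.05 these 6 lists had 0, 2, 2, 1, 1 and 0 members higher and 0, 0, 2, 0, 0 and 1 lower, and voom called 1 germ cell gene. In a fit of the 6-somites libraries alone they had 0, 3, 0, 1, 1 and 2 members higher and 0, 0, 3, 0, 1 and 5 lower.

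limma called 560 of 14755 genes in double morphants at 6-somites, 262 higher and 298 lower, and 2588 had an unadjusted p under 0.05. The count was 2897 in a fit of the 6-somites libraries alone. The balance turned with the setting, to 168 higher and 77 lower with a filter at 5 RPKM and 228 and 152 at a pseudocount of 0.1, against 299 and 482 at a pseudocount of 5. The count was 73 without double morphant 1 to 224 without double morphant 2 when any 1 of the 4 libraries was left out. All 37 named genes were called in the fit of the 6-somites libraries alone, and 11 kept their call whichever library was left out, among them fabp2, slc26a1, kdr, cdh17 and ccnb2, while the other 26 reached 0.056 to 0.43.

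**Figure D5:**
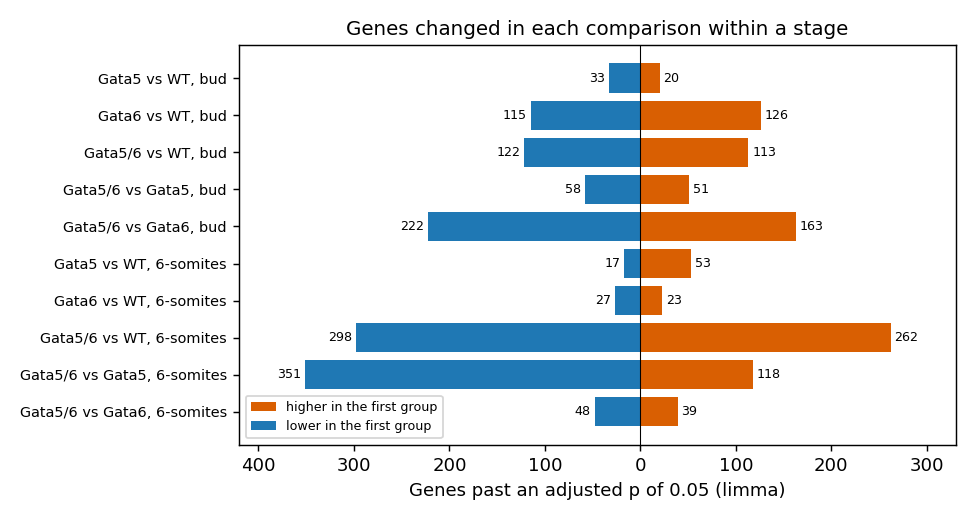
Number of genes past an adjusted p of 0.05 by limma (horizontal axis, genes) in the 10 comparisons within a stage, with bars to the right for genes higher and to the left for genes lower in the first group named. The longest bars were the 351 genes lower in double than in Gata5 morphants and the 298 lower in double morphants than in WT, both at 6-somites.

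Against single morphants at 6-somites, the double morphants again had less fabp2, at 14.1 ± 3.0 RPKM against 225 ± 21 RPKM in Gata5 and 127 ± 0.4 RPKM in Gata6 morphants (-3.91 and -3.09 ± 0.46). Against Gata5 morphants, ppp1r3ab (-2.62 ± 0.32), dao (-2.37 ± 0.44) and mafbb (-2.26 ± 0.38) were lower, and proz (2.18 ± 0.33), cdh17 (10.8 ± 0.85 against 2.1 ± 0.038 RPKM, 1.92 ± 0.21), kcnip3b (1.81 ± 0.35) and zgc:112994 (1.79 ± 0.32) were higher. Against Gata6 morphants, ppp1r3ab (-2.02 ± 0.32), acsl5 (-1.9 ± 0.29) and the bile salt transporter gene abcb11a (5.71 ± 1.2 against 23.7 ± 1.8 RPKM, -1.89 ± 0.24) were lower, and zgc:56231 (2.59 ± 0.15), basp1 (1.51 ± 0.28), gata5 (1.43 ± 0.11) and slc26a1 (1.41 ± 0.21) were higher. tmem88a was not past the threshold against Gata5 (-0.12 ± 0.3, adjusted p = 0.88) or Gata6 morphants (-0.59 ± 0.3, adjusted p = 0.46), nor was tmem88b (-0.52 ± 0.14, adjusted p = 0.072, and -0.26 ± 0.14, adjusted p = 0.5).

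Against Gata5 morphants at 6-somites limma called 469 genes, 118 higher and 351 lower, and 2653 had an unadjusted p under 0.05. Against Gata6 morphants it called 87, 39 higher and 48 lower, and 1835 had an unadjusted p under 0.05. With a filter at 5 RPKM the latter split was 36 higher and 25 lower. The counts were 2989 and 1618 in a fit of the 6-somites libraries alone, 838 and 146 with no filter, and 747 and 145 at a pseudocount of 5. The count against Gata5 morphants was 111 with a filter at 5 RPKM and 187 at a pseudocount of 0.1, and the count against Gata6 morphants was 141 with the block. When any 1 of the 4 libraries was left out, the counts were 39 without double morphant 1 to 156 without double morphant 2 against Gata5 morphants, and 4 to 12 for the same omissions against Gata6 morphants. cdh17, fabp2 and ppp1r3ab against Gata5 morphants, and zgc:56231 and gata5 against Gata6 morphants, kept their calls whichever library was left out.

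At 6-somites the double morphants departed from the sum of the single responses in 2 genes. kidins220, a scaffold gene of neurotrophin signalling, was at 0.668 ± 0.082 RPKM in double morphants, 3.81 ± 0.69 RPKM in Gata5 morphants, 2.96 ± 0.043 RPKM in Gata6 morphants and 3.41 ± 0.22 RPKM in WT (-1.36 ± 0.17, adjusted p = 0.03). fabp4a, a fatty acid binding protein gene named after its values were seen, was at 5.14 ± 0.85 RPKM in double morphants and at 0.351 ± 0.019 to 0.559 ± 0.29 RPKM in the other 3 groups (1.85 ± 0.22, adjusted p = 0.03). limma had 931 genes at an unadjusted p under 0.05 in that test. The count of 2 was 0 with the block, 319 in a fit of the 6-somites libraries alone, 5 with limma-voom, 5 with median-of-ratios scaling, 4 with no filter, 0 with a filter at 5 RPKM, and 0 and 9 at pseudocounts of 0.1 and 5. It was 0 without WT 6-somites 1 to 2 without Gata6 6-somites 2 when 1 of the 8 libraries was left out, and kidins220 lost its call in all 8 omissions, with adjusted p up to 0.6.

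WT embryos at 6-somites were compared with WT at bud as the background of normal development. tal1 rose from 0.328 ± 0.19 to 17.5 ± 0.5 RPKM (3.81 ± 0.13), en2 from 0.335 ± 0.097 to 16.5 ± 1.1 RPKM. The eye and midbrain gene mab21l2 rose from 1.69 ± 0.86 to 28.8 ± 3.5 RPKM, and thbs4, a matrix thrombospondin gene, from 0.324 ± 0.12 to 13.5 ± 2.7 RPKM. The Nodal antagonist gene lft2 fell from 12.5 ± 2.0 to 0.264 ± 0.15 RPKM (-3.41 ± 0.17), vrtn from 22.9 ± 12 to 1.77 ± 0.077 RPKM. The amino acid transporter gene slc3a2 fell from 124 ± 51.0 to 14.6 ± 3.5 RPKM, and frzb from 15.4 ± 3.0 to 1.25 ± 0.35 RPKM. Each of these genes kept its call whichever of the WT libraries was left out. limma called 4404 of 14751 genes, 2994 higher and 1410 lower, and 6000 had an unadjusted p under 0.05. Median-of-ratios scaling moved the higher share from 68% to 56.8%, a filter at 5 RPKM gave 2364 genes, and leaving out 1 library gave 2351 without WT 6-somites 1 to 4052 without WT bud 1.

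The double morphant effect differed between the stages in 1 gene, fabp4a (2.19 ± 0.22, adjusted p = 0.0087), at 0.147 ± 0.1 RPKM in double morphants at bud and 5.14 ± 0.85 RPKM at 6-somites against 0.154 ± 0.014 and 0.351 ± 0.019 RPKM in WT. It did not meet all limits of the naming rule. The next smallest p were for ENSDARG00000086281 (-2.25 ± 0.3) and zgc:194209 (-1.63 ± 0.23), both with adjusted p = 0.057. For nkx2.5, tbx20 and kdr that difference was thus not past the threshold. limma had 1286 genes at an unadjusted p under 0.05, and the count of 1 was 3 with the block, 15 with no filter, 12 at a pseudocount of 5, and 0 with a filter at 5 RPKM, with limma-voom, at a pseudocount of 0.1 or without both doubted libraries. It was 0 without double morphant bud 1 to 37 without double morphant bud 2, and fabp4a lost its call without double morphant bud 1 or WT 6-somites 1, with adjusted p up to 0.08.

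Gata5 and Gata6 morphants shared 2 called genes at bud, acsbg1, an acyl-CoA synthetase gene, higher in both (0.94 and 1.06), and arl3, a ciliary GTPase gene, lower in both (-0.88 and -0.77). Independent lists would share 0.17 and 0.26 genes, and 100 simulations of unchanged groups against shared WT libraries gave a mean and a highest count of 0. Unchanged groups yield hardly any calls, so that simulated count is no benchmark for lists that hold calls. A further 2 genes moved in opposite directions. Across genes, which are not independent replicates, the covariance of the log2 changes was 0.0262 at bud against 0.024 in the simulation and 0.0143 at 6-somites against 0.0239. The simulation used a spread pooled over both stages and no pairing of replicates, so its covariance is not specific to a stage. In a test added after the data were seen, Gata5 and Gata6 morphant libraries were each compared with a WT library of their own replicate number, so that no library was shared. The covariance over both ways to assign them was -0.0197 and 0.00801 at bud and 0.0151 and -0.00173 at 6-somites. Its sign thus depended on the libraries, and no shared response over all genes was established. By list at 6-somites, camera at its preset correlation called p53 and yolk genes higher and BMP signalling and neural plate genes lower in both. Those calls rest on the same WT libraries, and the other lists called were called in a single kind of morphant.

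At 6-somites the single morphants shared 0 genes called by limma, and 0 by voom. At an unadjusted p under 0.05, 130 were higher in both, 68 lower in both and 57 opposite, against 145, 219 and 80 at bud, where voom shared 4. How many of these the shared WT libraries alone would give was not computed. With separate WT libraries the counts higher, lower and opposite were 19, 91 and 106 or 66, 36 and 38 at bud, and 58, 17 and 6 or 19, 10 and 41 at 6-somites. The shared count at bud and at 6-somites was 14 and 7 at an adjusted p of 0.1, 6 and 0 with the block, 4 and 0 with median-of-ratios scaling, and 0 and 148 in fits of a stage alone. Double morphants shared 13 higher and 14 lower genes with Gata5 morphants and 21 and 23 with Gata6 morphants at bud, and 29 and 12 with Gata5 and 20 and 17 with Gata6 morphants at 6-somites. These comparisons share the WT libraries. Across genes, the log2 changes of double morphants correlated with those of Gata5 and Gata6 morphants at 0.45 and 0.43 at bud and 0.41 and 0.58 at 6-somites. The simulation of unchanged groups gave 0.5. Genes called at both stages were 12 higher and 7 lower in Gata5 morphants, 13 and 16 in Gata6 morphants, and 61 and 44 in double morphants, where independent lists would share 2 and 2.5, and none was called in opposite directions. The fit gave each gene the same spread at both stages, which alone raises such overlap, so independence is no strict baseline.

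The 25 called list results among 132 had the same sign of mean, median and test. With an estimated correlation 0 were called, fry called 5 and its mixed test 64, and with the block 26 were called.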

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

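The test of p53 genes in double morphants and the test of a diluted Gata6 morpholino effect were chosen after the result was seen. The other 4 tests in this part were written down before their results.

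A test of the departure from the sum of both single morphant effects singled out 4 genes at bud, en2 (-1.74 ± 0.16), tal1 (-1.86 ± 0.18), ntn1 (-1.13 ± 0.16) and a gene that is not named (-1.22 ± 0.16). At 6-somites the same test singled out fabp4a (1.85 ± 0.22) and kidins220 (-1.36 ± 0.17). A test of the change of the double morphant effect between stages singled out fabp4a (2.19 ± 0.22). For en2 and tal1 the negative sign arose because both genes were raised in Gata6 morphants at bud, to 2.82 ± 0.1 and 2.5 ± 0.23 RPKM, and not in double morphants. Both genes also rose in WT from bud to 6-somites, so a later stage of the Gata6 embryos at bud stays open. All 4 bud genes had means under 3 RPKM in every group at bud, so the log2 values depend on the pseudocount.

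Libraries of a group differed more at bud than at 6-somites. Embryos of a group collected at slightly different times would make the replicate difference follow the WT change between stages. The median absolute correlation across 1097 genes was 0.10, with -0.1 in Gata5, 0.31 in Gata6 and -0.02 in double morphants at bud. This argues against timing as a cause common to these groups, but leaves it open in Gata6 morphants. The WT libraries at bud were not part of the test, so timing stays open there too. On the first component, which separated the stages, the WT bud libraries scored -24.6 and -39.6, further apart than those of any other bud group. Gata5 bud libraries scored -30.5 and -23.8, Gata6 -14.6 and -26.9, and double morphants -37.3 and -36. At 6-somites, where libraries differed less, the correlations were -0.32, 0.04 and -0.4 in Gata5, Gata6 and double morphants. Lower depth would matter little for genes with many reads, but the ratio of SD between bud and 6-somites was 1.88 over 2818 genes with at least 1000 reads in each library and 1.99 over all 14751 genes. This argues against depth. Differences between clutches or injections stay open, because the labels give neither, and no biological explanation was tested.

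Double morphants at 6-somites had 560 changed genes, and a delay of these embryos is a possible explanation. Of the 560 genes 51.4% lay within the interval between WT at bud and WT at 6-somites, below the 80% set for a delay and above the 50% set against it. Of the 560, 479 differed from WT towards the WT bud value, 475 (84.8%) when the stage change came from a single WT library not used for the morphant effect. A delay acts on genes that change between stages. Of the 383 called genes that also changed between WT stages, 359 (93.7%) differed towards bud and 75.2% lay within the interval. The WT libraries at 6-somites entered both comparisons. Both WT libraries also served to call the 560 genes, so splitting them afterwards leaves that selection in place and is no separate evidence. On an axis of stage genes the median positions were 97.7% in Gata5, 83.1% in Gata6 and 75.5% in double morphants. General toxicity with a p53 response would raise p53 genes most in double morphants, but 13 of 20 were lower there than in both single morphants, with medians of 0.61 and 0.45 in Gata5 and Gata6 morphants and 0.31 in double morphants. At bud the p53 list was called in double morphants with the block alone (0.0489, against 0.0624 without it and 0.754 with an estimated correlation). The p53 test was made on seen values and its members move together, so toxicity stays open, as do delay and a direct effect on GATA targets.

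Genes lower in Gata6 morphants at both stages numbered 16, among them rexo2. Parental haplotypes that differ between clutches would place such genes near each other, and 0 pairs lay within 20 genes of each other in the gene order of build GRCz12tu. The test is void, because 12 of the 16 (75%) could be placed, under the 80% required, and random sets had a median of 0. An effect of the Gata6 morpholino that is diluted in double morphants is a candidate explanation. For the 115 genes lower in Gata6 morphants at bud, the ratio of the mean change at 6-somites in double over single morphants was 0.48 (95% interval 0.34 to 0.62 over 10000 bootstrap draws, for genes only). A first version took the median of the ratios per gene over genes that moved the same way by a minimum size in single morphants at 6-somites. No call was required at 6-somites, and the choice rests on the denominator of the ratio, which can lower the ratio. The first version gave 0.58 over 41 genes lower and 0.97 over 46 genes higher in Gata6 morphants, with 36 and 24 of them below 1. Genes higher in Gata6 morphants thus showed little dilution in that version. The ratios were 0.78 for genes higher in Gata6 morphants, 0.78 for genes higher in Gata5 morphants and 0.45 for genes lower in Gata5 morphants, so a lower dose of each morpholino, an opposing effect of the Gata5 morpholino and haplotypes all stay open, and the doses are not in the labels.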

How the results depend on the processing

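Leaving out both doubted libraries was chosen after the result was seen. Among 182 results for single genes, 1799 of 2279 values under the alternatives kept direction and side of the threshold, 456 lost the threshold, 18 passed it and 6 reversed. The reversed values were of genes not called: in Gata6 morphants at bud tmem88a ran from -0.56 without Gata6 bud 1 to 0.64 without Gata6 bud 2, with -0.16 without WT bud 2, and tmem88b from -0.01 without Gata6 bud 2 to 0.48 without Gata6 bud 1. tmem88b in double against Gata6 morphants at bud ran from -0.29 to 0.2 without Gata6 bud 1 or 2. tmem88a for the departure from additivity at bud ran from -1 to 0.2 without Gata6 bud 2 or 1, and tmem88b in Gata5 morphants at 6-somites from -0.14 to 0.03 without WT 6-somites 2 or 1. DESeq2 was not run.

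In fits of a stage alone the counts were 1 for Gata5, 0 for Gata6 and 6 for double morphants against WT at bud, 0 for double against Gata5 and 0 against Gata6 morphants at bud, and 0 for additivity at bud. At 6-somites they were 1271, 964 and 2897 against WT, 2989 and 1618 for double against Gata5 and Gata6 morphants, and 319 for additivity, and shared genes of single morphants were 0 at bud and 148 at 6-somites. Each such fit takes its spread from its own stage, which is larger at bud, and of the genes called at 6-somites over all libraries 69 of 70, 50 of 50 and 555 of 560 were called again. The 6-somites fit holds the same libraries and differences with a smaller spread. These repeats, and those of the named genes, are therefore no separate evidence. With the replicate block the counts were 88, 472 and 362 against WT at bud, 7 and 0 for additivity at bud and 6-somites, 115 for Gata5 morphants and 141 for double against Gata6 morphants at 6-somites, 3 for the change between stages, and 6 shared genes at bud. Without both doubted libraries they were 27, 409 and 87 against WT, 35 and 241 for double against Gata5 and Gata6 morphants at bud, and 0 for the change between stages.

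A filter at 5 RPKM, which tested fewer genes, gave 69 for double against Gata5 morphants at bud, 37, 28 and 245 against WT and 111 for double against Gata5 morphants at 6-somites, 0 for additivity at 6-somites, 2364 for WT between stages and 0 for the change between stages. No filter gave 255 for double against Gata6 morphants at bud, and at 6-somites 121 for Gata5 morphants, 838 and 146 for double against Gata5 and Gata6 morphants, 4 for additivity, and 15 for the change between stages. A pseudocount of 0.1 gave 46 for additivity at bud, 32 for Gata6 morphants, 187 for double against Gata5 morphants and 0 for additivity at 6-somites, and 0 for the change between stages. A pseudocount of 5 gave 0 for additivity at bud, and at 6-somites 127 and 98 for Gata5 and Gata6 morphants, 747 and 145 for double against Gata5 and Gata6 morphants, 9 for additivity, and 12 for the change between stages. limma-voom gave 414 for Gata6 morphants at bud, 38 and 5 for additivity at bud and 6-somites, and 0 for the change between stages. Median-of-ratios scaling gave 17 and 5 for additivity at bud and 6-somites, and 4 shared genes at bud. At an adjusted p of 0.1 the shared genes were 14 at bud and 7 at 6-somites. Of the list tests 0 were called with an estimated correlation, 5 by fry and 64 by its mixed test. Where no reason is given here, the cause was not tested.

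Leaving out any 1 library gave, at bud, 8 to 29 genes for Gata5, 17 to 2224 for Gata6 and 61 to 385 for double morphants against WT, 16 to 235 and 146 to 2123 for double against Gata5 and Gata6 morphants, and 2 to 988 for additivity. At 6-somites it gave 3 to 9, 1 to 2 and 73 to 224 against WT, 39 to 156 and 4 to 12 for double against Gata5 and Gata6 morphants, and 0 to 2 for additivity. It gave 2351 to 4052 for WT between stages, 0 to 37 for the change between stages and 19 to 33 list tests. For genes, only libraries of the groups compared were left out, and for list tests each of the 16. A lone library is assumed to vary like the other groups.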
